A study of Mus musculus with 9 samples.

How the data were processed

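Total RNA from flash-frozen breast tumours of mice was sequenced as strand-specific libraries, per the labels' protocols, and 9 tumour samples were given, 3 labelled AAV-Control and 6 labelled AAV-delta-mut-p53. The authors deposited 1 table of raw read counts per gene, with 1 column per tumour and Ensembl mouse gene identifiers as rows. STAR 2.6.0b, DESeq2 and the genome build GRCm38 are listed in the submitters' processing notes, with no role or order. The counting program, its strand setting, the gene annotation release and any filter on reads are not given in the sources used here. The deposited counts were whole numbers and were used as they stood. Each column was tied to its sample through the sample title, and 0 columns were left without a sample.

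The table held 49585 genes. Symbols were found for 49326 of the identifiers after the version suffix was removed, and 43749 identifiers matched with their version. Gene positions were taken from GENCODE mouse release 21 on GRCm38, which may not be the release the authors counted with. Reads of a gene with close copies elsewhere can be split or lost in counting, so values of Rpl21, immunoglobulin genes, casein genes, haemoglobin genes and histone genes are uncertain in size.

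Totals ran from 18581545 to 30953250 counts per tumour. The 3 control libraries were deeper than each of the 6 others, and counts were therefore scaled by library size and by TMM factors. CPM in the text are a gene's counts as a share of its library, on a fixed scale, with TMM factors unless stated otherwise. A gene was tested when edgeR's filterByExpr kept it, with its default minimum count of 10, which left 19606 genes. Differences were tested with edgeR 4.0.16 in R 4.3.3, by the 2-sided quasi-likelihood test with no covariate, and adjusted by the Benjamini-Hochberg method at a false discovery rate (FDR) of 0.05. Log2 fold changes are AAV-delta-mut-p53 over AAV-Control, and their standard errors (SE) come from the same fit. Trp53 was also compared by an exact 2-sided permutation test of log2(CPM + 1) over the 84 assignments of 3 tumours among 9.

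A set of 35 gene lists for pathways, cell types and RNA quality was fixed before the data were examined, as were the tests and the rule for naming genes. The lists held 608 distinct genes, of which 564 were tested. Each list was tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, 2-sided, adjusted over the 35 lists. The same lists were tested with a correlation estimated for each list and with fry, a rotation test of whether the genes of a list move one way on balance. A list mean is the mean log2 CPM of its tested members in 1 tumour, and groups of list means were compared by the exact permutation test over the same 84 assignments.

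The named genes were 9 fixed ones (Trp53, Mdm2, Cdkn1a, Mgst3, Prdx6, Gpx4, Slc7a11, Nfe2l2 and Acsl4), the 4 genes with the smallest unadjusted p in each direction, the 4 members with the smallest p of each list past its test, and 2 members of each other list. The text gives only a part of the genes that this rule names, and 1 of them is not reported here. For the genes by smallest p, gene models without a usual symbol and immunoglobulin or T-cell receptor segments were left out, and a mean of at least 1 CPM was required. The rule would have taken 8 genes per direction by fold change had that many passed the FDR threshold.

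The edgeR test, DESeq2 and camera with the preset correlation were tested on simulated counts with the means, spreads and library sizes of these 9 tumours, with 50 genes changed at each of 4 sizes, and the other tests were not. For AAV-delta-mut-p53 against AAV-Control, over 19142 simulated genes, edgeR recovered 0 of 50 genes at a log2 change of 1, 8 at 2, 21 at 3 and 32 at 4, with 0 calls among 18919 unchanged genes. DESeq2 1.42.0 recovered 3, 30, 38 and 47 of 50 at the same sizes and made 103 calls among the unchanged genes. In the same simulation camera called a list of 24 genes shifted by 1 on the log2 scale (FDR = 1.2e-11) and 1 list that had not been shifted. The simulated genes were drawn independently, so this does not show how camera behaves with correlated genes. In the data the estimated correlation differed between lists, from 0.008 for ferroptosis promoters and responses to 0.874 for interferon-stimulated genes, to name 2 of them.

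Alternatives set before the data were examined were other library scaling, DESeq2, limma voom with sample quality weights, a robust fit, other filters, the sum of the pair of samples titled 1284, each tumour left out in turn, and 1 surrogate variable from sva 3.50.0. DESeq2 without AAV-delta-mut-p53 2 was added after the data had been seen. Runs of neighbouring genes were searched among 11712 protein-coding genes with a mean of at least 5 CPM, scaled by library size alone, and were not part of the design set beforehand. No 2 libraries were alike within sampling noise, since the chi-square statistic per degree of freedom of the closest pair was 119. The labels do not say whether each sample came from its own animal. AAV-delta-mut-p53 4 and 5, titled 1284T1 and 1284T2, share a number in their titles and may come from the same mouse. The p-values therefore measure the spread between these samples, which may not be the spread between animals. No sequencing batch or date is given in the labels.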

Results

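Spontaneous breast adenocarcinomas of mice were profiled by RNA sequencing after injection of adeno-associated virus (AAV), a vector used to carry genes into tissue. The mice carried K14-Cre, which is active in keratin 14-positive epithelium, and a Cre-dependent Cas9 gene. Their Trp53 genotype was labelled wm-R172H/fl. The genotype label does not spell out wm or say which cells carry R172H. R172H is a missense change in the DNA-binding part of p53. Tumours received AAV on days 0, 3 and 8 and were collected when the animals met the criteria for euthanasia. The interval from injection to collection is not given in the sources used here. There were 3 AAV-Control tumours and 6 AAV-delta-mut-p53 tumours, in which the vector was meant to delete mutant p53. Total counts were 26954188, 30953250 and 26280250 in AAV-Control 1 to 3, and 21129054, 22011438, 21705106, 18581545, 21300166 and 24567423 in AAV-delta-mut-p53 1 to 6.

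The first comparison asked how much RNA of the targeted gene remained. RNA of Trp53 (ENSMUSG00000059552.13), from chromosome 11, 69580359 to 69591873 on GRCm38, was present in every tumour. It was 43.4 ± 4.71 CPM (SD, n = 3) in AAV-Control and 32.4 ± 11.9 CPM (SD, n = 6) in AAV-delta-mut-p53 tumours. Control tumours held 48.6, 39.3 and 42.3 CPM. AAV-delta-mut-p53 1 held 13.1 CPM and AAV-delta-mut-p53 2 held 22.0 CPM, both below every control tumour, while numbers 3 to 6 held 39.0, 37.8, 40.9 and 41.5 CPM, within the control range or just under it. The log2 fold change was -0.42 (95% confidence interval -1.24 to 0.40), and Trp53 did not pass edgeR's quasi-likelihood test (FDR = 0.78). The exact 2-sided permutation test gave p = 0.131, where 0.0119 is the smallest p that 84 assignments allow. Counts per gene do not separate the R172H transcript from an edited one, so they measure the amount of Trp53 RNA and not the presence of the edit. The RNA came from whole tumours, so Trp53 RNA of cells other than tumour cells is counted too. AAV-delta-mut-p53 2 also held 25400 CPM of the muscle gene Ttn. Its lower Trp53 value cannot be told apart from a different make-up of that sample.

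The next comparison concerned genes that p53 controls and genes of glutathione and lipid peroxide metabolism, which the study addresses. None of the 9 fixed genes passed edgeR's test, with FDR of at least 0.677. Mdm2, the ubiquitin ligase that removes p53 and is itself a p53 target, had the largest difference among the p53 genes, at 252 ± 268 CPM (SD, n = 3) in controls and 82.7 ± 16.5 CPM (SD, n = 6) in AAV-delta-mut-p53 tumours. That difference rested on AAV-Control 3, which held 561 CPM while the other controls held 90.9 and 103 CPM. The log2 fold change was -1.61 (SE 0.51) with all tumours and -0.24 without AAV-Control 3. Cdkn1a, the p53 target that encodes the cell cycle inhibitor p21, was 7.55 ± 3.64 CPM (SD, n = 3) in controls and 9.75 ± 6.10 CPM (SD, n = 6) in the other group. Its log2 fold change was 0.37 with all tumours, 0.16, 0.84 and 0.19 without AAV-Control 1, 2 and 3, and 0.02 without AAV-delta-mut-p53 6.

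Mgst3, a microsomal glutathione transferase, was 9.51 ± 3.17 CPM (SD, n = 3) in controls and 17.8 ± 8.50 CPM (SD, n = 6) in AAV-delta-mut-p53 tumours, a log2 fold change of 0.91 (SE 0.47). Gpx4, the peroxidase that reduces lipid hydroperoxides, had a log2 fold change of 0.63 (SE 0.35), and Prdx6, a peroxiredoxin, one of 0.33 (SE 0.31). The value of Gpx4 was 0.42 without AAV-delta-mut-p53 6, and that of Prdx6 was 0.67 without AAV-Control 1 and 0.04 without AAV-Control 3. Slc7a11, the cystine importer, was 2.99 ± 1.89 CPM (SD, n = 3) against 6.71 ± 3.16 CPM (SD, n = 6), with a log2 fold change of 1.17 that was 1.79 without AAV-Control 3. Nfe2l2, which encodes the oxidative stress regulator NRF2, was 93 ± 15.3 CPM (SD, n = 3) against 120 ± 30.9 CPM (SD, n = 6). Acsl4, which loads polyunsaturated fatty acids into membrane lipids, reached 720 CPM in AAV-delta-mut-p53 3 and 557 CPM in AAV-delta-mut-p53 6, and lay between 38.9 and 147 CPM in the other tumours.

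**Figure D1:**
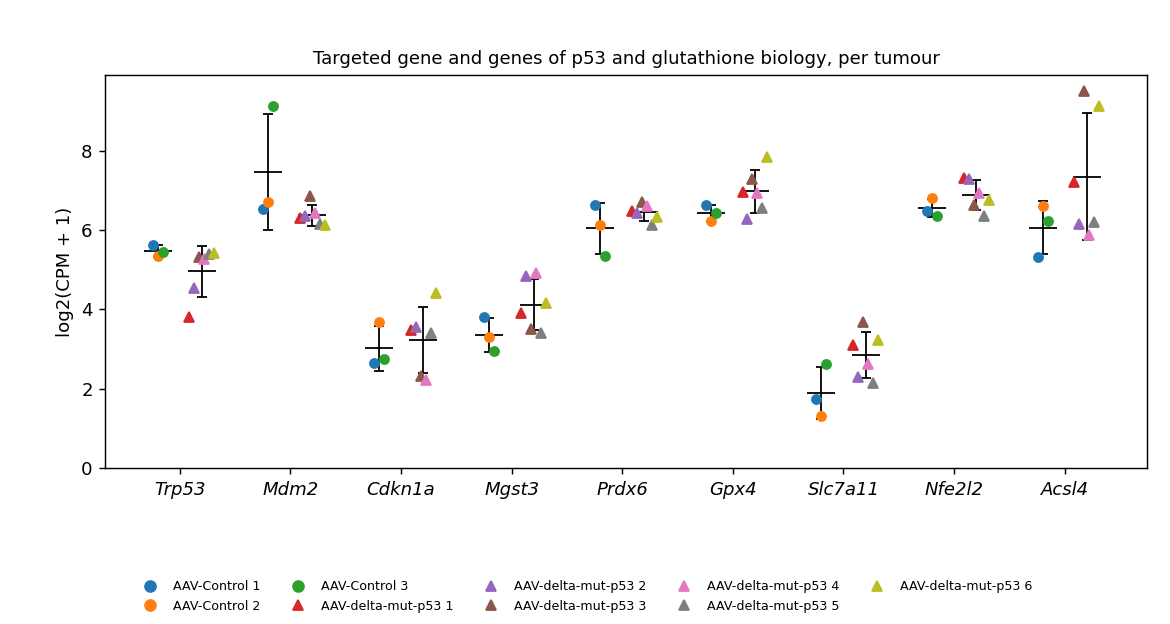
Expression of the 9 fixed genes in each tumour, as log2(CPM + 1) on the vertical axis, with circles for the 3 AAV-Control tumours, triangles for the 6 AAV-delta-mut-p53 tumours and bars for the mean and SD of each group. Trp53 is lowest in AAV-delta-mut-p53 1, at 13.1 CPM, and Mdm2 is highest in AAV-Control 3, at 561 CPM.

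The p53 target list and the ferroptosis lists were compared as groups. Of 32 p53 targets, 12 were higher and 20 lower in AAV-delta-mut-p53 tumours, and the list did not pass camera (FDR = 0.183), except without AAV-Control 3 (FDR = 0.0474). Of 34 NRF2 targets and glutathione genes, 20 were higher and 14 lower (FDR = 0.68), with Mgst2 at 0.41 CPM in controls and 7.32 CPM in the other group and Gclm, a subunit of glutamate cysteine ligase, at 113 and 57.8 CPM. Of 27 ferroptosis suppressors, 18 were higher and 9 lower (FDR = 0.43). The 1 member with an unadjusted p under 0.05 was Cbs, a transsulfuration enzyme gene, which was lower at 25.3 and 4.69 CPM, with a log2 fold change of -2.43 that was -1.04 without AAV-Control 3. The list of 25 ferroptosis promoters and responses was higher (FDR = 0.041 by camera; adjusted p = 0.679 with an estimated correlation), with 19 members higher and 6 lower. Its mean log2 CPM was 4.39 ± 0.29 (SD, n = 3) in controls and 4.83 ± 0.23 (SD, n = 6) in the other group, a difference with an exact permutation p of 0.0357 that did not hold after adjustment over the 35 lists (adjusted p = 0.555 by permutation). Besides Acsl4, the members with the smallest p were Chac1, a glutathione-degrading enzyme, Gls2, a glutaminase, and Alox15, a lipoxygenase that reached 32.6 CPM in AAV-delta-mut-p53 2. Without that tumour the log2 fold change went from 2.70 to 1.3 for Alox15 and from 1.70 to 1.04 for Chac1. In edgeR's test none of the members of these 4 lists passed the FDR threshold over all genes or adjusted over the list alone. DESeq2 called Mgst2 among them (FDR = 0.00879 by DESeq2). The camera call of the ferroptosis promoters was lost without any 1 of AAV-Control 1, AAV-Control 2, AAV-delta-mut-p53 3, 5 or 6, with FDR between 0.0532 and 0.154, and also with no filter on low counts (FDR = 0.144), with a stricter one (FDR = 0.105) and with genes of more than 1 list removed (FDR = 0.0942).

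Across all genes none passed edgeR's threshold, and among the genes that the naming rule takes, Cxcl13 had the smallest p on the higher side and Gpc2 on the lower side. Cxcl13, a chemokine that draws B cells, on chromosome 5 from 95956951 to 95961068, was 0.44 ± 0.04 CPM (SD, n = 3) in controls and 7.37 ± 5.18 CPM (SD, n = 6) in AAV-delta-mut-p53 tumours. Saa3, an acute-phase serum amyloid, was 1.96 ± 2.19 CPM (SD, n = 3) and 22.1 ± 10.5 CPM (SD, n = 6). Gpc2, a heparan sulfate proteoglycan of the glypican family on chromosome 5 from 138273655 to 138280005, was 10.5 ± 4.51 CPM (SD, n = 3) and 0.64 ± 0.49 CPM (SD, n = 6). The groups of Cxcl13 and of Gpc2 did not overlap, while AAV-delta-mut-p53 5, at 4.20 CPM of Saa3, lay below AAV-Control 3 at 4.48 CPM. The log2 fold change of Saa3 was 3.50 with all tumours and 4.97 without AAV-Control 3. Over all tested genes, 288 had every AAV-delta-mut-p53 tumour above every control and 312 had every one below, where chance gives 2.38% of genes in both directions together.

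The other genes with the smallest p on the higher side were Helz2, a helicase induced by interferon, with a log2 fold change of 2.08 (SE 0.46), and Serpinb8, a protease inhibitor, with 2.23 (SE 0.56). On the lower side they were Lhfpl1 (log2 fold change -4.55, SE 0.87), Rflna (-3.30, SE 0.65) and Rpl21 (-2.27, SE 0.42), a ribosomal protein gene with many processed pseudogenes. Without AAV-Control 2 the values were -2.37 for Rflna and -3.91 for Lhfpl1. The smallest FDR of edgeR's quasi-likelihood test was 0.677 over 19606 genes, and 0 genes passed 0.05. At an unadjusted p under 0.05 there were 1387 genes, 748 higher and 639 lower, where 980 are expected with no effect. That count was 874 without AAV-Control 2, 842 among the fewer genes left by a stricter filter on low counts and 2443 among the larger number with no filter. Limma voom with sample quality weights called 0 genes, with a smallest FDR of 0.0761 and 2038 genes at an unadjusted p under 0.05. DESeq2 had 1922 genes at an unadjusted p under 0.05.

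DESeq2 called 104 genes, 60 higher and 44 lower in AAV-delta-mut-p53 tumours, of which 16 of the higher ones were immunoglobulin genes. Without AAV-delta-mut-p53 2, DESeq2 called 261 genes, 98 of them among the 104. In simulated counts with these spreads DESeq2 made 103 calls among 18919 unchanged genes, and edgeR made 0. Those counts also held changed genes, so how many of the 104 calls are false cannot be read from them. Among the named genes DESeq2's calls included Cxcl13, Gpc2, Lhfpl1, Ltf, Saa3, Igkc, Helz2, Mgst2 and Zbp1, and none of the 9 fixed genes.

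Genes that respond to interferon were higher in AAV-delta-mut-p53 tumours as a group, in 4 of the 6. All 28 interferon-stimulated genes had a higher mean, by a median log2 fold change of 2.03, and 19 had an unadjusted p under 0.05 in edgeR's test. The mean log2 CPM of the list was 3.48 ± 0.49 (SD, n = 3) in controls and 4.94 ± 1.63 (SD, n = 6) in the other group. It was 5.82, 6.19, 5.97 and 5.98 in AAV-delta-mut-p53 2, 3, 4 and 6, and 2.78 and 2.90 in numbers 1 and 5, which lay below the control tumours at 4.02, 3.37 and 3.05. Zbp1, a sensor of left-handed nucleic acid, was 5.88 ± 0.60 CPM (SD, n = 3) in controls and 43.9 ± 37.6 CPM (SD, n = 6) in the other group. Ifih1, an RNA sensor, was 31.7 and 124 CPM, Mx2, an antiviral GTPase, 3.10 and 16.6 CPM, and Herc6 8.80 and 31 CPM.

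The interferon-stimulated list passed camera (FDR = 1.9e-09; adjusted p = 0.696 with an estimated correlation), and the exact permutation test of its means gave p = 0.167. Antigen presentation and the interferon gamma response followed the same tumours, with 23 of 24 members higher (FDR = 1.2e-06 by camera; adjusted p = 0.696 with an estimated correlation). Cd74, the invariant chain of class II molecules, was 82.0 ± 43.2 CPM (SD, n = 3) in controls and 347 ± 263 CPM (SD, n = 6) in the other group. Cxcl10, an interferon-induced chemokine, was 1.93 and 8.55 CPM, and the guanylate-binding protein genes Gbp3 and Gbp2 were 21 and 75.9 CPM and 19.0 and 62.8 CPM. In edgeR's test none of the members of either list passed the FDR threshold over all genes or adjusted over the list alone. DESeq2 called Zbp1 among them (FDR = 0.0474 by DESeq2).

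Markers of several leukocytes were also higher. All 11 neutrophil genes tested had a higher mean (FDR = 3.1e-06 by camera; adjusted p = 0.696 with an estimated correlation), and the list mean was 0.52 ± 1.75 (SD, n = 3) against 2.62 ± 1.1 (SD, n = 6), with an exact permutation p of 0.0476 (adjusted p = 0.555 by permutation). Ltf, which encodes the iron-binding protein lactoferrin found in neutrophil granules and in milk, was 4.51 ± 1.48 CPM (SD, n = 3) in controls and reached 390 CPM in AAV-delta-mut-p53 6, 263 CPM in number 3 and 233 CPM in number 1. The interleukin gene Il1b was 3.18 and 17.9 CPM, the cytokine receptor gene Csf3r 4.75 and 15.4 CPM, and Acod1, the source of itaconate, 0.95 and 8.91 CPM. The log2 fold changes of Il1b and Acod1 were 2.5 and 3.23 with all tumours and 3.97 and 4.97 without AAV-Control 3. Of 13 B and plasma cell genes, 11 were higher (FDR = 0.0275 by camera; adjusted p = 0.869 with an estimated correlation), and Igkc, the kappa light chain, was the 1 member that passed adjusted over the list alone, at 17.0 ± 2.39 CPM (SD, n = 3) and 183 ± 148 CPM (SD, n = 6).

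Of 18 macrophage and monocyte genes, 17 were higher (FDR = 0.041 by camera; adjusted p = 0.898 with an estimated correlation), with Cd14, the endotoxin co-receptor, at 13.4 and 58.7 CPM and the complement gene C1qc at 47.5 and 103 CPM. Cd14 had a log2 fold change of 2.14 with all tumours and 1.48 without AAV-delta-mut-p53 3. The B cell and macrophage calls were lost without AAV-delta-mut-p53 2, with FDR of 0.359 and 0.468. The B cell call was also lost without AAV-Control 1 (FDR = 0.0815), AAV-Control 2 (FDR = 0.0503) or AAV-delta-mut-p53 4 (FDR = 0.0989), and the macrophage call without AAV-Control 1 (FDR = 0.169), AAV-Control 2 (FDR = 0.148), AAV-delta-mut-p53 3 (FDR = 0.0546) or AAV-delta-mut-p53 6 (FDR = 0.102), with 1 surrogate variable (FDR = 0.123) and with no filter on low counts (FDR = 0.0657). T cells (FDR = 0.58 by camera), NK and cytotoxic cells (FDR = 0.70), dendritic cells (FDR = 0.62) and mast cells (FDR = 0.60) did not pass. Hdc, which makes histamine, was the 1 mast cell gene that passed adjusted over the list alone, at 1.22 and 6.14 CPM. AAV-delta-mut-p53 2 had the highest mean of the T, NK, B, macrophage, dendritic and mast cell lists among the 9 tumours.

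Milk genes had higher means in AAV-delta-mut-p53 tumours, though not every tumour was above the controls for each gene. Of 11 milk secretion genes in the list, 5 were tested. Of these, 4 were higher and all 4 passed adjusted over the list alone. Over all genes 0 passed edgeR's threshold, with 4 at an unadjusted p under 0.05 and Btn1a1 and Csn2 called by DESeq2. Csn1s1 and Csn2, which encode caseins, were 0.66 and 0.18 CPM in controls and 77.1 and 7.16 CPM in the other group, where Csn1s1 reached 433 CPM in AAV-delta-mut-p53 3. Its log2 fold change was 6.88 with all tumours, 3.18 without that one and 8.21 without AAV-Control 3. Xdh had a log2 fold change of 2.49 with all tumours and 1.59 without AAV-delta-mut-p53 2, and Btn1a1 3.75 with all tumours and 2.70 without AAV-delta-mut-p53 6. Csn2 had 5.25 with all tumours and 4.35 without AAV-delta-mut-p53 3. At 0.135 and 0.0815 CPM in AAV-delta-mut-p53 1 and 6, Csn2 lay within the control range of 0.0667 to 0.246 CPM. The other AAV-delta-mut-p53 tumours held at least 1.79 CPM of Csn2. Btn1a1, a milk fat globule protein, was 0.86 ± 0.35 CPM (SD, n = 3) against 11.6 ± 15 CPM (SD, n = 6), and Xdh, needed for milk fat release, was 37.5 and 211 CPM. The list passed camera (FDR = 1.6e-03; adjusted p = 0.679 with an estimated correlation), with a list mean of 1.88 ± 0.52 (SD, n = 3) against 4.15 ± 1.64 (SD, n = 6) and an exact permutation p of 0.0476 (adjusted p = 0.555 by permutation). Mammary luminal epithelium (FDR = 0.86 by camera), basal and myoepithelial epithelium (FDR = 0.097) and differentiated keratinocytes (FDR = 0.66) did not pass with all tumours. The basal list passed, as lower, without AAV-Control 1 (FDR = 0.038), AAV-delta-mut-p53 4 (FDR = 0.0125) or AAV-delta-mut-p53 6 (FDR = 0.0424), and the keratinocyte list, as lower, without AAV-Control 2 (FDR = 0.00254). With all tumours 8 of the 15 basal genes were higher and 7 lower, with a median log2 fold change of 0.11 although camera's direction was down. Trp63, the basal epithelial regulator, was 419 ± 157 CPM (SD, n = 3) in controls and 105 ± 80.7 CPM (SD, n = 6) in the other group, and was lowest, at 3.47 CPM, in AAV-delta-mut-p53 3.

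Cell cycle and endothelial genes were lower by camera, while the exact permutation test of their list means gave p = 0.25 and p = 0.155. Of 29 cell cycle genes, 26 had a lower mean (FDR = 2.8e-04 by camera; adjusted p = 0.869 with an estimated correlation), with a median log2 fold change of -0.34. Mki67, the proliferation antigen, was 1251 ± 273 CPM (SD, n = 3) in controls and 702 ± 240 CPM (SD, n = 6) in the other group, and the centromere histone gene Cenpa was 85.8 and 41.9 CPM. The thymidylate synthase gene Tyms was 67.7 and 39.6 CPM and the spindle motor gene Kif11 363 and 190 CPM. The list mean was 4.69 in AAV-delta-mut-p53 2 and between 6.12 and 6.58 in the other 8 tumours, and without AAV-delta-mut-p53 2 the list did not pass (FDR = 0.0865 by camera).

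Of 13 endothelial genes, 11 were lower (FDR = 2.9e-04 by camera; adjusted p = 0.696 with an estimated correlation), and 2 passed adjusted over the list alone. These were Cdh5, the endothelial cadherin, at 130 ± 48.5 CPM (SD, n = 3) in controls and 52.1 ± 19.8 CPM (SD, n = 6) in the other group, and the tight junction gene Cldn5, at 22.4 and 5.35 CPM. Cldn5 was 45.3 CPM in AAV-Control 1 and 5.19 CPM in AAV-Control 3, and its log2 fold change was -2.06 with all tumours and -1.04 without AAV-Control 1, when the list had an FDR of 0.0488 by camera. Erg, an endothelial transcription factor, was 14.5 and 5.81 CPM, and Pecam1, which encodes CD31, was 105 and 55.4 CPM. Pericytes (FDR = 0.21 by camera), Schwann cells and nerve (FDR = 0.21), erythroid cells (FDR = 0.21) and adipocytes (FDR = 0.70) did not pass with all tumours, and erythroid cells passed, as lower, without AAV-Control 2 (FDR = 0.00254). Fibroblasts and matrix did not pass either (FDR = 0.62), and camera's direction was down while the median log2 fold change was 0.37. They passed, as lower, without AAV-delta-mut-p53 2 (FDR = 0.00671) or AAV-Control 3 (FDR = 0.0387).

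**Figure D2:**
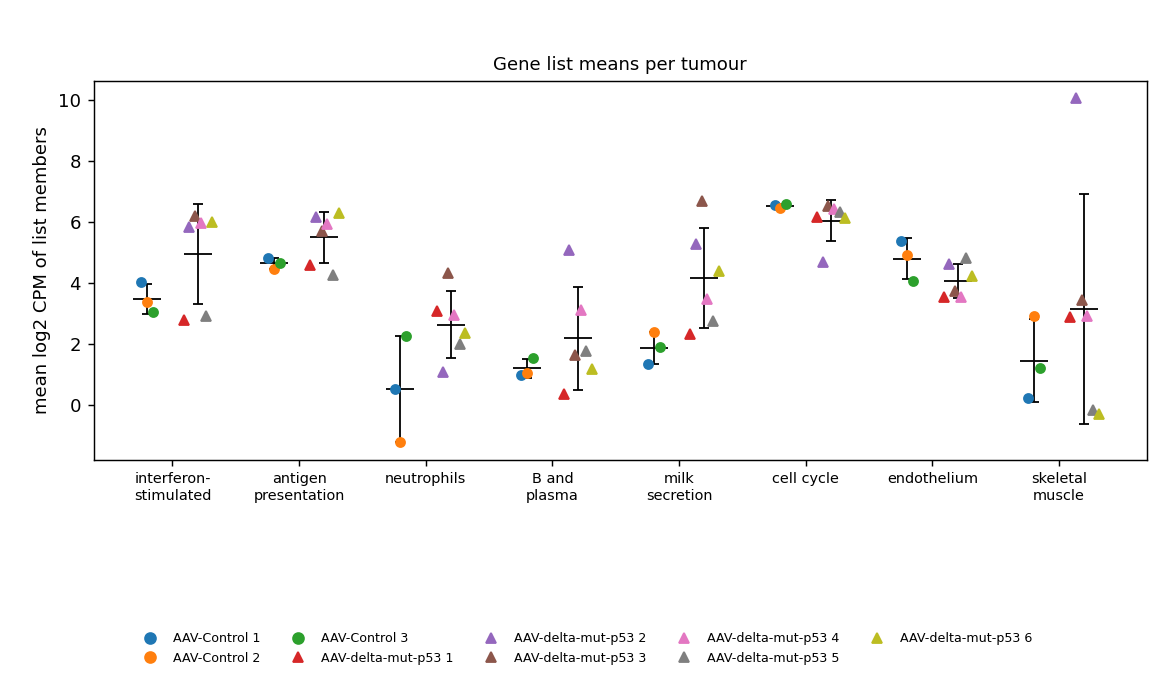
Mean log2 CPM of the members of 8 gene lists in each tumour, with circles for the 3 AAV-Control tumours, triangles for the 6 AAV-delta-mut-p53 tumours and bars for the mean and SD of each group. The interferon-stimulated list is at 5.82 to 6.19 in 4 AAV-delta-mut-p53 tumours and at 2.78 and 2.90 in the other 2, and the skeletal muscle list is at 10.05 in AAV-delta-mut-p53 2.

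Immediate early genes, which are induced by stress and by tissue handling, were higher (FDR = 0.015 by camera; adjusted p = 0.696 with an estimated correlation), with 10 of 12 members higher. Atf3 was 13.3 and 37.5 CPM, Dusp1 11 and 29.0 CPM, Junb 21.5 and 59.7 CPM and Jun 56.9 and 123 CPM. The log2 fold change of Atf3 was 1.5 with all tumours and 2.22 without AAV-Control 3, and that of Junb 1.47 and, without AAV-Control 1, 2.25. Skeletal muscle genes passed as well (FDR = 0.041 by camera; adjusted p = 0.898 with an estimated correlation), through 1 tumour. Titin RNA (Ttn) was 25400 CPM in AAV-delta-mut-p53 2 and at most 203 CPM elsewhere, and the myosin gene Myh4 was 6290 CPM against at most 28.7 CPM. Mylpf, a myosin light chain, and Atp2a1, the muscle calcium pump, were 858 and 914 CPM in that tumour. Without it the muscle list did not pass (FDR = 0.598 by camera), nor without AAV-Control 1 (FDR = 0.299), AAV-Control 3 (FDR = 0.0869), AAV-delta-mut-p53 3 (FDR = 0.0546) or AAV-delta-mut-p53 4 (FDR = 0.0513), with no filter on low counts (FDR = 0.0572) or with a stricter one (FDR = 0.194).

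The integrated stress response (FDR = 0.17 by camera), hypoxia and glycolysis (FDR = 0.068), cholesterol synthesis (FDR = 0.58), epithelial to mesenchymal transition (FDR = 0.64), cell death mediators (FDR = 0.64) and oxidative phosphorylation (FDR = 0.58) did not pass with all tumours. Hypoxia and glycolysis passed, as higher, without AAV-Control 3 (FDR = 0.00146), AAV-delta-mut-p53 3 (FDR = 0.0333) or AAV-delta-mut-p53 5 (FDR = 0.00325) and with the 2 samples of 1 title number summed (FDR = 0.0167). Cholesterol synthesis passed, as higher, without AAV-delta-mut-p53 2 (FDR = 0.00671). Mitochondrially encoded genes (FDR = 0.70), heat shock genes (FDR = 0.87) and replication-dependent histones (FDR = 0.15) did not pass either, except that the histones passed, as lower, without AAV-Control 3 (FDR = 1.1e-04) or AAV-delta-mut-p53 4 (FDR = 0.0125). Bcl2l1, which encodes the survival protein BCL-XL, was 28.5 ± 7.89 CPM (SD, n = 3) in controls and 76.7 ± 28.9 CPM (SD, n = 6) in the other group. Xiap, an inhibitor of caspases, went the other way, at 201.9 and 113.5 CPM, and 11 of the cell death mediators were higher and 10 lower. Aldoa, a glycolytic enzyme gene, was 371 and 918 CPM, and Trib3, a pseudokinase gene of the stress response, 4.11 and 12.3 CPM. Stc2 was 277 CPM in AAV-Control 1 and at most 26.8 CPM in the other tumours, and its log2 fold change went from -2.77 to 0.73 without AAV-Control 1.

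In all, 11 of the 35 lists passed camera with the preset correlation, 9 higher and 2 lower. With a correlation estimated for each list 0 passed (smallest adjusted p = 0.679; 2 at an unadjusted p under 0.05), and with fry 0 passed (smallest adjusted p = 0.652; 2 at an unadjusted p under 0.05). Immediate early genes were not called without AAV-Control 3 (FDR = 0.114 by camera) or without AAV-delta-mut-p53 3 (FDR = 0.0532), or with genes of more than 1 list removed (FDR = 0.0525).

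The value of Mdm2 in AAV-Control 3 stood among raised neighbours. On chromosome 10, in the run of genes from 115197872 to 118168997, 16 of 21 protein-coding genes were highest in AAV-Control 3, by a median log2 ratio of 2.01 to the median tumour. Mdm2, at 117688875 to 117710758, lay in that run with Cct2, Frs2, Cpsf6 and Nup107. A run of the same kind on chromosome 6 in AAV-delta-mut-p53 3, singled out after its values were seen, held Met, which encodes the receptor of hepatocyte growth factor. Scaled by library size alone, Met was at 9180 CPM there and between 47.0 and 510 CPM in the other 8 tumours.

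**Figure D3:**
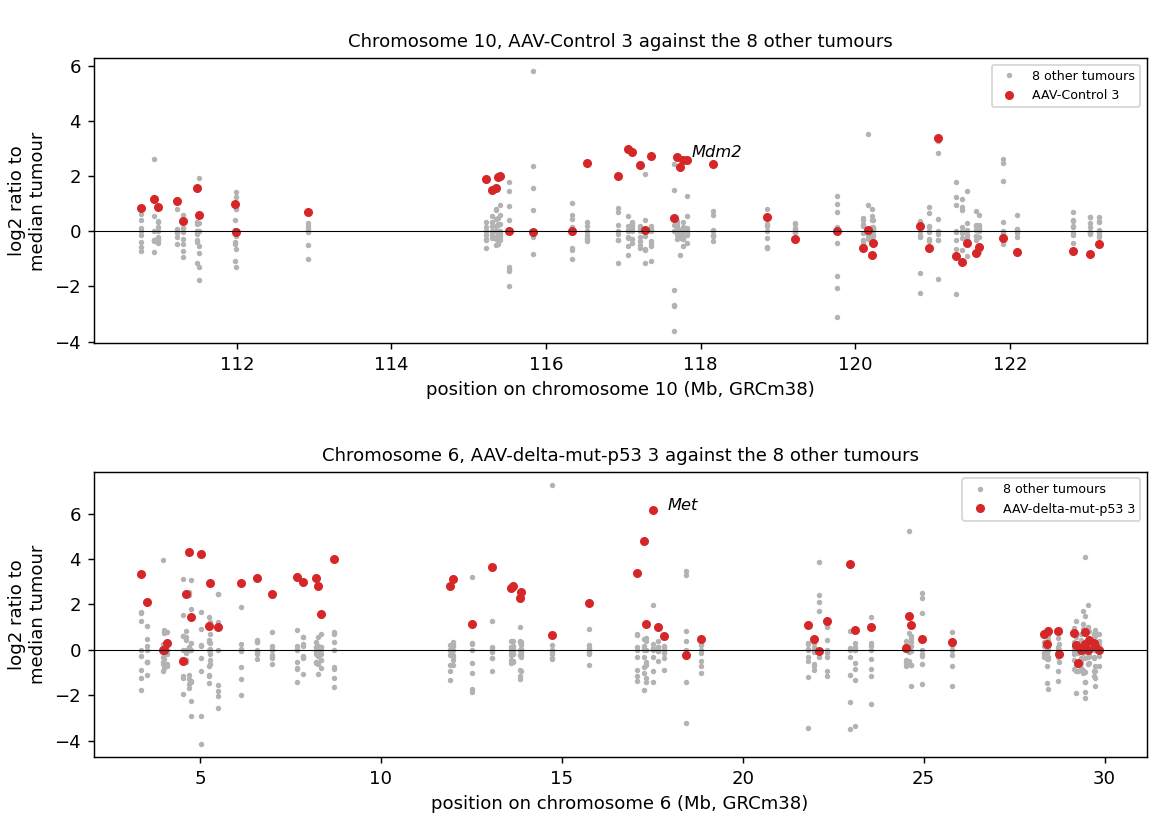
Expression of neighbouring genes along parts of chromosomes 10 and 6, as the log2 ratio to the median tumour for each protein-coding gene at its GRCm38 position, with AAV-Control 3 (top) and AAV-delta-mut-p53 3 (bottom) in red and the 8 other tumours in grey. Mdm2 lies in a run raised by a median of 2.01 in AAV-Control 3, and Met lies at 6.15 in AAV-delta-mut-p53 3.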

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

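Apart from planned results that are repeated here, all tests in this part were chosen after the values had been seen. In the 6 AAV-delta-mut-p53 tumours, 1 tumour lay far from the others, by the gap to its nearest neighbour as a share of the whole range, for 9 of 105 named genes and 5 of 35 lists. Chance gives about 5.2 and 1.8 if the values are normally spread. The counts are no test of chance, since genes of 1 list move together and the naming rule used the same values. Myh4, Atp2a1 and Ttn were named as members of the skeletal muscle list, which passed through AAV-delta-mut-p53 2. AAV-delta-mut-p53 2 was the tumour that lay apart for 5 of the genes and 4 of the lists. It was highest for the muscle genes Myh4 (share 0.755), Atp2a1 (0.651) and Ttn (0.651), for mt-Atp6 (0.697), and for the lists of skeletal muscle (0.639), fibroblasts and matrix (0.706) and dendritic cells (0.708). It was lowest for Gclm (0.65), at 28.7 CPM against at least 53.4 CPM in the other 5, and for the cell cycle list (0.787).

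Other tumours lay apart for single items. AAV-delta-mut-p53 3 was highest for Csn1s1 (share 0.668), at 433 CPM against at most 11.2 CPM, and lowest for the erythroid list (0.73). AAV-delta-mut-p53 5 was lowest for Saa3 (0.65), at 4.20 CPM, and for Serpinb8 (0.657), at 5.40 CPM. AAV-delta-mut-p53 6 was lowest for the prolactin receptor gene Prlr (0.638), at 6.19 CPM against at least 37.2 CPM.

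AAV-delta-mut-p53 2 had a mean correlation of 0.819 with the other tumours, which themselves ranged from 0.874 to 0.899, and was highest of the 9 for 9 of 18 cell type lists. A lower share of tumour cells with every other cell type raised alike is argued against by 1 gap. The endothelial list was 0.34 above the mean of the other 8 tumours while the fibroblast list was 3.13 above it. That gap was -2.79, where its SD in the other 8 was 0.45. The test covers an equal rise only, so a lower share of tumour cells with an uneven rise stays open. Relative to the mean of the other 8, the mammary luminal list was at -1.37 and the basal list at -1.53, where the SDs in the other 8 were 0.91 and 1.11. The luminal mean was the lowest of the 9, at 3.86, while AAV-delta-mut-p53 3 had a lower basal mean, at 3.17 against 4.13. Skeletal muscle in the sample remains open as a source of the muscle RNA, since all 13 of 13 tested muscle markers were highest there, led by Ttn at 25400 CPM. Muscle tissue alone is not known to bring B cell RNA, and whether lymphoid and fat tissue next to the tumour came with it was not tested. No group in the labels separates this tumour from the others, so no biological explanation was tested.

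The interferon-stimulated list was higher in AAV-delta-mut-p53 tumours by 1.46 (SE 0.99) in mean log2 CPM. AAV-delta-mut-p53 2 alone is argued against as its source, because 3 of the 5 other AAV-delta-mut-p53 tumours, at 6.19, 5.97 and 5.98, had a list mean above every control tumour. With the mean of the T cell, NK and macrophage lists as a covariate the difference was 1.29 (SE 0.95), so more leukocytes in these tumours cannot be told apart from a difference at equal leukocyte content, with standard errors this wide. The deletion itself also stays open and untested, as does chance, with an exact permutation p of 0.167.

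Splits of the 9 tumours into 3 and 6 say nothing of the 0 genes past edgeR's threshold, since 84 of 84 splits must give at least 0 (the highest of the others gave 5). Chance could not be excluded for the other counts. As many as the 1387 genes at an unadjusted p under 0.05 by edgeR (874 without AAV-Control 2) were given by 30 of the 84 splits, with 3071 as the highest of the others. The 104 genes of DESeq2 were reached by 6 of 24 splits, drawn at random with the real one included, and the highest of the others was 1050. That split set AAV-delta-mut-p53 2, 3 and 6 apart, and the 4 other drawn splits with AAV-delta-mut-p53 2 and 6 in the group of 3 gave 725, 403, 228 and 77 genes. The counts several times the real one point to a structure of the samples, whose nature was not tested. Not every split with AAV-delta-mut-p53 2 and 6 in the group of 3 had a high count. Each drawn split that reached 104, other than the real one, had AAV-delta-mut-p53 2 in the group of 3. With that tumour in the group of 6, as in the real split, the highest of the other drawn splits gave 88 genes. At least 11 lists passed camera with the preset correlation in 57 of 84 splits, with 22 as the highest of the others.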

How the results depend on the processing

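Most choices were set before the data were examined; DESeq2 without AAV-delta-mut-p53 2 was added afterwards. The count of genes by edgeR stayed at 0 under other scaling, other filters, a robust fit, a surrogate variable, an FDR of 0.10, the sum of the samples that share a title number and each tumour left out, and limma voom with quality weights also gave 0 (2038 at an unadjusted p under 0.05). The 1387 genes at an unadjusted p under 0.05 by edgeR became 842 with the stricter filter, 2443 with no filter and between 874 (without AAV-Control 2) and 2009 (without AAV-delta-mut-p53 5) as each tumour was left out. DESeq2 called 104 genes (60 higher, 44 lower), and 261 (124 and 137) without AAV-delta-mut-p53 2, and the cause was not tested. DESeq2 also made 103 calls among unchanged genes in simulated counts. Those counts held changed genes as well, so 103 is not the number to expect where no gene changes. The log2 fold change of Trp53 ran from -0.59 to -0.25 over all alternatives and passed no test. The count of 11 lists ran from 8 to 13 as each tumour was left out, and was 0 with an estimated correlation and 0 with fry, both of which count the correlation between genes. The interferon-stimulated list kept its call in every alternative but those 2. The surrogate variable was 0.923 in AAV-delta-mut-p53 2 and between -0.207 and 0.031 in the other tumours, so it mostly marks that tumour. A random block for the title number could not be estimated, since only 2 samples share one, and gave no value. The list test works on log2 CPM, so another gene-wise test does not alter it and was not run for it. No paired analysis was possible because the labels give the groups no shared replicate numbers.

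Of 1948 values of single named genes under alternatives, 12 had the other sign, where edgeR had called no gene with all tumours. Of 624 list values, 33 had the other direction. A list called with all tumours lost its call in 52 of those values, and a list not called gained one in 15. As each tumour was left out, the log2 fold change ran from -1.51 to 0.29 for Alas2, -1.62 to 0.20 for Hba-a1, -3.33 to 0.73 for Stc2, -0.34 to 2.39 for Cma1, -0.42 to 3.02 for Col6a1 and -0.08 to 6.88 for Myh4. Stc2 turned without AAV-Control 1, Alas2 and Hba-a1 without AAV-Control 3, and the others without AAV-delta-mut-p53 2. With DESeq2 and without that tumour Cma1 was at -0.35, Col6a1 at -0.41 and Myh4 at -0.09. With quality weights Cma1 was at -1.19 and Col6a1 at -0.16, and with a surrogate variable Cma1 was at -0.05.

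Lists that turned in direction had these FDR ranges by camera as each tumour was left out: mammary luminal 0.169 to 0.887, mitochondrial 0.109 to 0.978, heat shock 0.598 to 0.941, NK 0.285 to 0.991, mast cells 0.156 to 0.673, adipocytes 0.216 to 0.987, T cells 0.119 to 0.880, dendritic cells 0.448 to 0.987, epithelial to mesenchymal transition 0.339 to 0.834, NRF2 targets 0.420 to 0.812, fibroblasts 0.00671 to 0.973, keratinocytes 0.00254 to 0.918 and erythroid cells 0.00254 to 0.655. Mammary luminal also turned with the stricter filter (0.765), the summed samples (0.991) and the surrogate variable (0.724). With that variable NK, mast cells and adipocytes turned (0.979 each). Without a filter the mitochondrial (0.971) and heat shock lists (0.965) turned, and with the stricter filter the mitochondrial list (0.725). With shared genes removed NRF2 targets (0.857) and heat shock (0.953) turned. The cause was not tested. In simulated counts with these depths, spreads and group sizes edgeR recovered 0 of 50 genes changed by 1 on the log2 scale and 8 of 50 changed by 2; the part of depth in this was not tested.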

Other observations

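All tests in this part, and the genes it names, were chosen after the values had been seen. CPM here are scaled by library size alone. Some genes differed by tumour more than by group, and those named here lay in runs of neighbouring genes raised in the same tumour. Brinp3 was 482 CPM in AAV-delta-mut-p53 6 and at most 1.43 CPM in the other 8 tumours. It lies in the run of that tumour on chromosome 1 from 143598800 to 150108227. Cnn1, a smooth muscle calponin gene, was 422 CPM in AAV-delta-mut-p53 4 and at most 110 CPM elsewhere. Icam1, a leukocyte adhesion gene, was 200 CPM there and at most 28.5 CPM elsewhere. Cnn1 and Icam1 lie in the run of AAV-delta-mut-p53 4 on chromosome 9 from 20428449 to 27357546, so they are not observations separate from it.

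Runs of neighbouring genes were raised together in single tumours. With a window of 15 protein-coding genes and a median log2 ratio of at least 1.5 to the median tumour, 28 runs were found, 25 higher and 3 lower, in 8 of the 9 tumours. AAV-delta-mut-p53 3 had 37 genes on chromosome 6 from 3372257 to 17666972 raised by a median of 2.74, of which 28 were highest of the 9 tumours, among them Met, Cav2 at 2910 CPM against at most 146 CPM, and Tes at 1840 CPM against at most 286 CPM. AAV-delta-mut-p53 4 had 64 genes on chromosome 9 from 20428449 to 27357546 raised by 1.71, 56 of them highest of the 9. AAV-delta-mut-p53 1 had 36 genes on chromosome 11 from 113649169 to 115823094 raised by 2.40, and AAV-delta-mut-p53 6 had 26 genes on the same chromosome from 3131850 to 4928867 raised by 1.93, 25 of them highest of the 9.

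A part of chromosome 8 was raised in tumours of both groups. Cul4a, a ubiquitin ligase scaffold gene at 13105621 to 13147940, was 391 CPM in AAV-Control 3 and 1230, 1560 and 631 CPM in AAV-delta-mut-p53 1, 4 and 5, and between 91.7 and 207 CPM in the other 5 tumours. Of its 20 nearest expressed neighbours, 17 were raised by at least 1 on the log2 scale in AAV-delta-mut-p53 1 and in number 5, and 10 in AAV-Control 3 and in number 4. Lamp1, which lies beside it, reached 6530 CPM in AAV-delta-mut-p53 4.

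Chance order of the genes is argued against for these runs, since 0 of 100 shuffled gene orders gave as many and the highest number was 1. In AAV-delta-mut-p53 2 the runs may come from families of related genes that lie side by side and belong to 1 cell type, because the share of distinct name stems in its 7 runs had a median at percentile 1.4 of all windows of the same size. In the other tumours the median of 21 runs was at percentile 49.7, near the middle of all windows. In 19 of these 21 runs under 0.5 of the genes can share a name stem, so families with shared names are not most of those runs. Relatives with different names would be missed. The bound is loose, since the only 2 runs outside it were at percentile 4.0 or below, and families stay open for those 2. The run with Met was at percentile 18.4 and that with Mdm2 at 19.2, so families as a part of such runs are not excluded. A candidate explanation for the higher runs outside AAV-delta-mut-p53 2 is a gain of DNA copies in single tumours, which would also account for the Mdm2 value of AAV-Control 3, but this is a hypothesis from RNA alone and DNA was not analysed here.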
